A study of Pseudopodoces humilis with 2 samples.

How the data were processed

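Total RNA of liver and muscle of the ground tit was made into libraries with Illumina's TruSeq RNA kit and sequenced on an Illumina HiSeq instrument, per the labels. TopHat, a spliced aligner, is named in the submitters' processing notes, and Cufflinks, a transcript assembler, is named in the assembly files. Their versions, the genome build, the annotation, the counting tool and the definition of gene length are not given in the sources used here.

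The authors deposited a table of RPKM per gene for liver and muscle, per the file headers. It also holds 3 rows that are not genes, for reads of no feature, ambiguous reads and reads aligned at more than 1 place. These were left out of all gene values. They held 24.3%, 0.0635% and 2.80% of the liver reads and 30.6%, 0.217% and 4.13% of the muscle reads, which left 72.8% and 65.0% for genes. The transcript assemblies give scaffold positions of transcripts and exons, 1-based. Per the deposited files, Cufflinks' score of a transcript lies between 100 and 1000. It compares transcripts within a locus only and was not used for abundance.

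Reads were recovered from the RPKM values, a step chosen after the data were examined. The values have up to 15 significant digits. The liver total was the smallest whole number for which all rows that are not genes came out as whole reads, at a length of 1, and the muscle totals followed from the most common ratios of muscle and liver values. All of these came out whole to within 2.05e-08. The muscle values could be written as the mean of the RPKM of 2 libraries. Per gene, the smallest whole length and reads that give both values within a relative 6e-15 were then searched, and 15380 of 15394 genes (99.9%) were solved. The 14 others were left out of read-based values. A factor shared by length and reads is lost, so lengths and reads are lower bounds, while RPKM per library does not depend on it. The solutions accounted for 91.6% of the liver reads left for genes and 95.1% of the muscle reads. On simulated liver and muscle data of 3891 genes, 92.9% were recovered exactly, 7.09% up to a shared factor, 0.0257% wrongly, and 0.0257% were not solved. The solutions accounted for 75.4% of the simulated liver reads. The muscle totals were given in the simulation, so finding them from common ratios was not simulated. Unchanged genes had the same level in both tissues, so genes at 0 in liver with many muscle reads were hardly covered. In the same simulation 100 of 100 genes raised 8-fold and 100 of 100 lowered 8-fold passed the 4-fold rule, and 0 unchanged genes did. The changed genes were given muscle levels well above the pseudocount of 1 RPKM, so their passing was largely set by the simulation. It does not show how many 8-fold changes of genes with low RPKM would pass. The simulation holds counting error and no spread between samples, so it does not measure how often unchanged genes would pass the rule in real samples. Between the 2 muscle libraries, 149 of 11747 genes with 20 or more reads in each were at least 4-fold apart, without a pseudocount.

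The difference between tissues was log2(liver RPKM + 1) minus log2(muscle RPKM + 1). The pseudocount of 1 understates differences of genes with low values. Genes with a difference of 2 or more, or of at least 2 in the other direction, were counted as 4-fold higher in liver or in muscle. No p-value was computed for the 2 tissues. A gene was detected at 1 RPKM or more. Counting intervals of RPKM are exact Poisson 95% intervals of the recovered reads. They and the floor of 3 reads cover counting error only, since reads without molecular identifiers are not independent molecules. Where a gene's reads hold a lost factor, its interval is too wide.

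The rule for named genes, set before the data were examined, was to name by symbol. Where the files pair no ID with a name, it was to give only the 2 largest differences in each direction. The files used here pair no ID with a name, so the latter applied, and 33 gene lists fixed in advance (tissue functions and markers of other cell types) were not evaluated. No reference genome or annotation was used here.

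Loci were made within each assembly by merging transcript spans that share at least 1 base on a scaffold, on either strand, with bedtools 2.31.1. Overlap between assemblies was counted with the same tool at 1 base or more. Shares have Wilson 95% intervals. Introns were compared by scaffold, both ends and strand. Calculations were done in Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1, and figures with matplotlib 3.10.9.

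Alternatives fixed before the data were examined were other pseudocounts, a filter at 5 RPKM, a scale on which both tissues have the same sum (TPM scale), centring, quantile normalization, each muscle library alone, other detection minimums, reads in place of RPKM, transcripts of 2 or more exons, transcripts of 200 bases or more and overlap of 50%. RPM (reads scaled to a common number of reads), subtraction of 0.590% of the liver RPKM from the muscle RPKM (the percentile 10 of the muscle shares under 5%), and scaling without the 50 highest genes were added after the data were examined. Other cuts on liver reads, the comparison of introns, of muscle libraries gene by gene, and of scaffolds with 1 listed gene, and shares by recovered reads, were also chosen then.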

Results

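The ground tit (Pseudopodoces humilis) is a ground-dwelling songbird of the Tibetan plateau. RNA sequencing of its liver and muscle was done to help annotate its genes, and the series holds 1 sample per tissue. The gene table gave RPKM (reads per kilobase of gene, scaled to a common number of reads) for 15394 genes on 2679 scaffolds. Transcripts assembled from the reads were given in 1 set for liver and 2 sets for muscle. With 1 sample per tissue there were no replicates, so no difference between the tissues was tested, and genes were separated by a fixed rule of size. The whole-number reads behind the RPKM values pointed to totals of 46313678 reads for liver, and 86472618 and 47542891 reads for the 2 libraries averaged in the muscle column. These are called the larger and the smaller muscle library here, since nothing tied them to the 2 muscle assemblies.

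On the deposited RPKM scale, more genes were detected in muscle than in liver. At 1 RPKM or more, 4777 genes were detected in liver and 6816 in muscle, with 4215 in both. A further 562 genes reached 1 RPKM in liver alone and 2601 in muscle alone. Of these, 4 of the liver genes were listed at 0 in muscle, and 113 of the muscle genes were listed at 0 in liver. A value of 0 in muscle requires 0 reads in both muscle libraries, which together hold more reads than liver. The counts of 4 and 113 are thus not on equal terms. The median gene had 0.302 RPKM in liver and 0.727 RPKM in muscle. The median gene had 124 recovered reads in liver, 599 in the larger and 274 in the smaller muscle library, although the liver total was close to that of the smaller muscle library. A count of 0 allowed up to 3 reads, which is 0.0648 RPM (reads scaled to a common number of reads, without the gene's length) in liver, 0.0347 RPM in the larger muscle library and 0.0631 RPM in the smaller.

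The summed RPKM was concentrated in a few genes. The 10 highest genes took 45.1% of the summed RPKM in liver and 34.5% in muscle, but 35.6% and 14.3% with recovered reads, which are lower bounds, in place of RPKM. By RPKM, the highest gene alone took 20.8% in liver and 12.3% in muscle, while by recovered reads another gene led in each tissue, with 12.4% and 3.27%. In liver 17 genes made up 50% of the sum, against 43 genes in muscle, and 37 and 338 genes made up 50% of the recovered reads. The highest liver gene stood at 24307 RPKM and at 795 RPKM in muscle. The highest muscle gene stood at 17935 RPKM and at 2953 RPKM in liver, and it was 1 of 3 genes found among the 10 highest of both tissues. In each tissue 6 of the 10 highest genes were at least 4-fold higher there than in the other tissue.

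Genes that differed between liver and muscle were found in both directions. On the scale of log2(RPKM + 1), 352 genes were at least 4-fold higher in the liver sample and 691 were at least 4-fold higher in the muscle sample. The liver-high genes had a median of 21.6 RPKM in liver and 0.789 RPKM in muscle, and together they took 58.5% of the liver sum and 1.34% of the muscle sum. The muscle-high genes had a median of 16.0 RPKM in muscle and 0.626 RPKM in liver, and they took 49.96% of the muscle sum and 4.54% of the liver sum. These shares add RPKM over genes of unlike length, and shares by recovered reads are not given for them. The median recovered length was 5800 bases for liver-high, 2835 for muscle-high and 8503.5 for all genes. Differences of 16-fold or more were found for 106 genes in the direction of liver and 148 in the direction of muscle. At 64-fold or more there were 34 and 36 genes, and at 256-fold or more 0 and 12 genes. The order at 256-fold was not kept when 0.590% of the liver RPKM was subtracted from the muscle RPKM of each gene. Then 19 genes were 256-fold or more higher in liver and 12 in muscle. That percentage was itself taken from the low muscle shares of well-covered liver genes. Genes near it keep little or no muscle RPKM, so the 19 depends on the pseudocount. Which direction held more genes at 256-fold was thus not settled. The excess of muscle-high genes depended on the scale: 66.3% of the genes past 4-fold were higher in muscle as deposited, but 44.5% (507 higher in liver, 407 in muscle) once the differences were centred on the genes detected in both tissues. The median difference of those genes was -0.57, liver minus muscle, and 75.9% of them had the higher value in muscle.

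**Figure D1:**
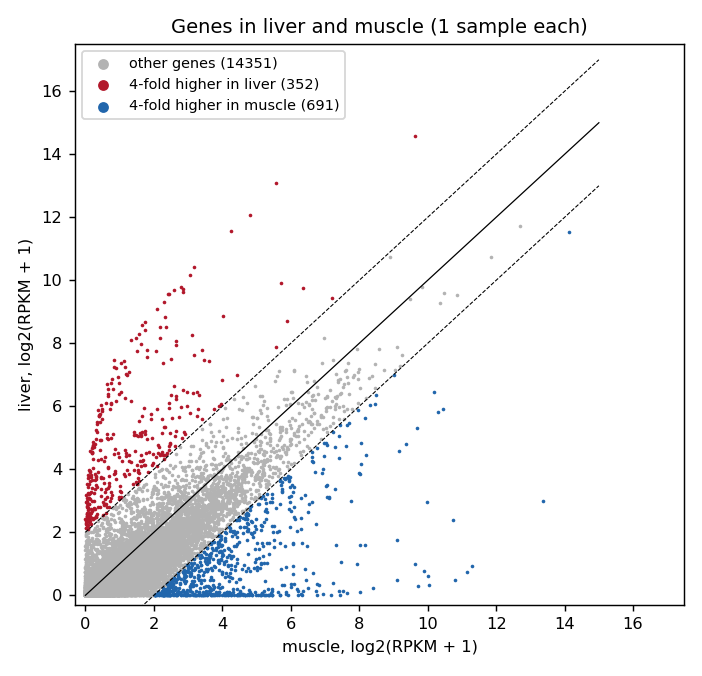
Each point is 1 gene, with muscle on the horizontal and liver on the vertical axis, both as log2(RPKM + 1). The solid line marks equal values and the dashed lines mark 4-fold differences, beyond which lie 352 genes higher in liver and 691 higher in muscle.

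The largest difference in the direction of liver belonged to evm.TU.scaffold11323.28, gene 28 on scaffold 11323. It stood at 8798 RPKM in liver, with an exact Poisson 95% interval of 8789 to 8806 for counting error, and at 33.1 RPKM (32.7 to 33.5) and 60.6 RPKM (59.9 to 61.3) in the larger and smaller muscle libraries. Its difference was 7.52, from 3836111 liver reads. Gene 2 on scaffold 9940, evm.TU.scaffold9940.2, followed with 3037 RPKM in liver (3028 to 3047) against 12.8 (12.3 to 13.2) and 23.2 (22.4 to 24.0) RPKM in the muscle libraries, a difference of 7.32. The muscle RPKM was 0.532% and 0.592% of the liver RPKM of these genes, near 0.521%, the lowest share of any gene with 5000 or more liver reads. With 0.590% of the liver RPKM subtracted from the muscle RPKM, their differences were 13.10 and 11.48, values that depend on the pseudocount because little or no muscle RPKM is left.

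In the direction of muscle, evm.TU.scaffold1358.1 and evm.TU.scaffold22797.29 had differences of nearly the same size, and their order turned with a pseudocount of 5 (-8.65 and -9.79) and with the larger muscle library alone (-10.17 and -10.20). The former is the only gene listed on scaffold 1358, with 0.681 RPKM in liver (0.274 to 1.40, from 7 reads) and 1935 RPKM (1915 to 1955) and 2629 RPKM (2598 to 2660) in the muscle libraries. Its difference was -10.41. On its scaffold the muscle assemblies held 2 and 1 transcripts, between positions 32 and 835, and the liver assembly held 0. The latter, gene 29 on scaffold 22797, differed by -10.37. It had 7.04 RPKM in liver (6.50 to 7.62, from 619 reads) against 9444 RPKM (9429 to 9459) and 11878 RPKM (11855 to 11900) in the muscle libraries. The files used here pair no ID with a gene name, so what these genes encode is not reported.

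The spread between the 2 muscle libraries was below the difference between the tissues. Across 11747 genes with 20 or more reads in each, the log2 RPM correlated with Pearson's r of 0.978 and Spearman's rho of 0.980, values across genes, which are not independent replicates. The SD of the log2 ratio between the libraries was 0.50, and 94.4% of genes lay within 2-fold. Between liver and muscle the same r was 0.654 over 10084 genes, with an SD of 1.86. Of the 352 liver-high genes, 334 were also 4-fold higher in liver against each muscle library alone, as 596 of the 685 solved muscle-high genes were 4-fold higher in each muscle library. The labels do not say whether the libraries came from separate birds, so their spread may be technical.

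Genes with many reads in liver also had reads in muscle. Among 594 genes with 5000 or more liver reads, 119 had a muscle RPKM under 5% of the liver RPKM and 70 had one under 1%. The lowest share was 0.521%, but 0.360% among the 2798 genes with 1000 or more liver reads. For those 70 genes the median share, in RPM, was 0.486% in the larger and 0.831% in the smaller muscle library. In the other direction, of 1873 genes with 5000 or more reads in the larger muscle library, 91 had a liver RPKM under 0.5% of the muscle RPKM, and the lowest was listed at 0.

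**Figure D2:**
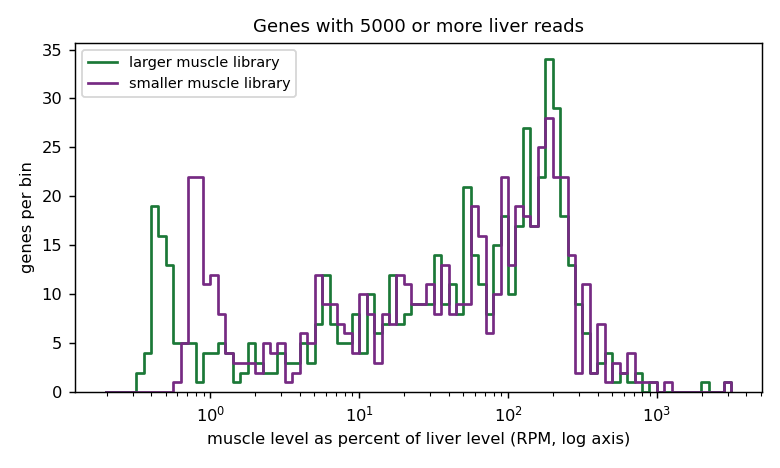
The horizontal log axis gives the level in each muscle library as a percent of the level in liver, both in RPM, and the vertical axis gives the number of genes per bin, for the 594 genes with 5000 or more liver reads. In each library the genes stop at a lower edge, at 0.317% in the larger and 0.616% in the smaller library.

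The assemblies added transcript structures in both tissues. Liver gave 23614 transcripts in 16579 merged loci, and the muscle assemblies gave 31092 transcripts in 21193 loci (muscle assembly 2) and 27092 in 18543 loci (muscle assembly 3). Transcripts of 1 exon made up 25.7%, 32.1% and 27.1% of them. Spliced transcripts had a median of 8 exons in each assembly, and the median spliced length over all transcripts was 1761, 1688 and 1739 bases. Exons covered 38.1 Mb in liver and 51.7 and 44.8 Mb in muscle. The transcript with the most exons, chosen after its values were seen, was found in both muscle assemblies on scaffold 22693. It had 145 exons, from position 422780 to 537194 in muscle assembly 2 and from 423093 to 537190 in muscle assembly 3, with 68544 and 68227 spliced bases. The liver transcript with the most exons had 93, on scaffold 10296 from position 408722 to 511309.

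Most of what was assembled in liver was also assembled in muscle. With loci of the muscle assemblies merged, 15473 of 16579 liver loci (93.3%, Wilson 95% interval 92.9 to 93.7) overlapped a muscle locus by at least 1 base. In the other direction, 12882 of 21041 muscle loci (61.2%, 60.6 to 61.9) overlapped a liver locus. The muscle assemblies overlapped each other at 78.6% (78.0 to 79.1) of the loci of assembly 2 and 95.9% (95.6 to 96.2) of those of assembly 3. Exact introns gave the same order: 98190 of 107293 liver introns (91.5%, 91.3 to 91.7) were found in muscle, and they made up 67.9% (67.6 to 68.1) of the 144707 muscle introns. Between the muscle assemblies, 83.9% of the introns of assembly 2 were in assembly 3, and 89.8% of those of assembly 3 were in assembly 2. Muscle had 2 assemblies against 1, and its recovered read totals (86472618 and 47542891) were above that of liver (46313678). Liver reads carried into muscle, a candidate given below, could also place liver loci in the muscle assemblies. The asymmetry between the tissues may thus reflect these limits, which were not separated.

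**Figure D3:**
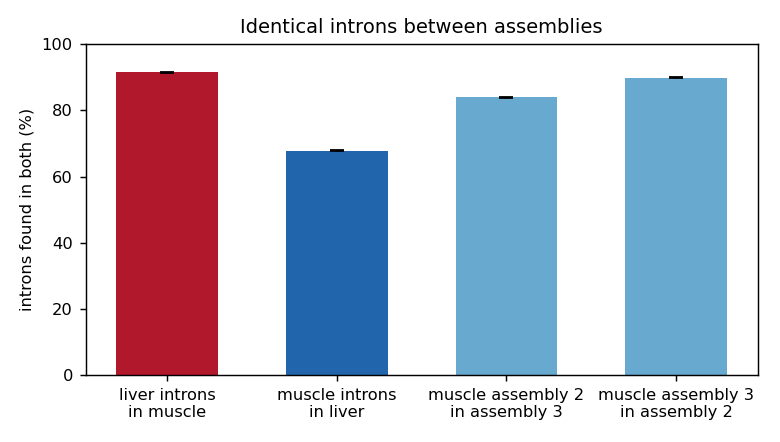
Bars give the percent of introns with identical ends and strand in another assembly, from 0 to 100%, and error bars are Wilson 95% intervals. Liver introns were found in muscle at 91.5%, and muscle introns in liver at 67.9%.

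The gene table and the assemblies could be set side by side on 1617 scaffolds with 1 listed gene. Of 37 such genes at least 4-fold higher in liver, 36 had a transcript on their scaffold in the liver assembly (97.3%, Wilson 95% interval 86.2 to 99.5), against 25 (67.6%, 51.5 to 80.4) and 26 (70.3%, 54.2 to 82.5) in the muscle assemblies. Of 98 genes at least 4-fold higher in muscle, 97 had one in each muscle assembly (99.0%, 94.4 to 99.8) and 41 had one in liver (41.8%, 32.6 to 51.7). Of the 1482 other genes, 737 (49.7%, 47.2 to 52.3) had a transcript in liver, and 1060 (71.5%, 69.2 to 73.8) and 933 (63.0%, 60.5 to 65.4) had one in the muscle assemblies. The reads behind the table and the assemblies are from the same samples, so this is not a replicate check.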

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

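All tests in this part were chosen after the patterns they bear on were seen. Only the one of the most abundant genes was written before its own result. Reads outside the gene rows formed the data that no comparison used. Reads of no feature made up 24.3% of the liver and 30.6% of the muscle reads, reads aligned at more than 1 place 2.80% and 4.13%, and ambiguous reads 0.0635% and 0.217%, all above what a count of 0 allows.

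Genes with 5000 or more liver reads kept at least 0.521% of their liver level in muscle, while a muscle gene with as many reads was listed at 0 in liver. The edge depends on that cut. With 1000 or more liver reads 10 genes lay below it, the lowest at 0.360%. Of these, 4 had fewer muscle reads than the 95% range of counting error around the median shares. Such a range leaves some genes outside it by itself, and 101 genes lay under 1%. Whether 1 exact share held for all genes is thus not decided by this count. Low expression of each gene in the muscle itself, at a level of its own, would leave the ratio between the muscle libraries like that of other genes of the same muscle level. For the 70 genes under 1% the median log2 ratio of smaller over larger library was 0.79 (SD 0.26), above the highest median, -0.0077, of 1000 random sets of 70 other genes matched on muscle level, which argues against that explanation. Liver RNA or reads carried into both muscle libraries would give these genes 1 ratio of their own, and their median was 0.88 above that of all other genes (-0.09, SD 0.50), with 69 of 70 higher in the smaller library (96 of 101 at 1000 or more liver reads). Carry-over near 0.486% and 0.831% of the liver level in the larger and smaller library is a candidate explanation; whether it arose at dissection, in library preparation or in sequencing was not tested, and a liver-like set of genes expressed together in muscle at different levels in the 2 libraries stays open.

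Few long genes passed 1 RPKM: in liver 11% of the longest of 5 equal length classes did, against 38.9% of the middle class. Long genes were not more often below 1 RPM in liver. The share with 1 RPM or more differed by -0.0975 percentage points, middle minus longest class (70.9% and 71.0%). But genes of the longest class (median recovered length 54712.5 bases) need far more than 1 RPM to reach 1 RPKM. This share thus does not decide whether fewer reads at higher levels contributed. On 682 scaffolds with 1 gene and 1 assembled region, the recovered length was 2.10 times the longest spliced transcript in the median (quartiles 1.11 and 4.95), and 0.842 times the assembled span (0.492 and 0.992). With transcripts of 3 or more exons the medians were 3.13 and 0.848, and 1114 genes had a recovered length above the longest spliced transcript, 68544 bases. The authors' division by the genomic span, introns included, is a candidate explanation; the first ratio lies close to the bound of 2 set for it, and RPKM then compares a gene between tissues but not genes with each other.

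Of the genes detected in both tissues, 75.9% had the lower RPKM in liver, with a median difference of -0.57. A larger share of reads outside genes in liver is argued against, because liver had the smaller share and scaling on the reads left for genes moved the median to -0.75. Scaling each tissue on its sum without the 50 highest genes of either moved it to -0.029. A few very abundant genes taking up the liver total may thus account for the shift. A tissue difference in the total amount of RNA stays open and untested, since RPKM is relative.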

How the results depend on the processing

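Alternatives with RPM, with subtracted carry-over or without the 50 highest genes were chosen after the data were seen. The counts past 4-fold, 352 in liver and 691 in muscle, became 630 and 2091 with a pseudocount of 0.1, 164 and 254 with a pseudocount of 5, 677 and 1482 on the TPM scale and 590 and 1791 with RPM, the muscle excess staying. Both the TPM scale and a low pseudocount give low genes more weight by construction. Rescaling turned the excess to liver under centring (507 in liver, 407 in muscle), quantile normalization (487 and 422) and scaling without the 50 highest genes (470 and 441). The filter at 5 RPKM, either muscle library alone and subtracted carry-over kept both counts within 1.5 times.

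Genes detected in liver, in muscle and in both went from 4777, 6816 and 4215 to 13935, 15216 and 13757 at any RPKM above 0, to 9753, 11587 and 9352 at 0.1 RPKM, to 1627, 2473 and 1182 at 5 RPKM, to 9492, 11055 and 8991 on the TPM scale and to 9308, 10939 and 8921 at 1 RPM. Muscle had more in every one of these. At any RPKM above 0 the comparison favours muscle, since a read in either muscle library is enough. Detection was not counted under centring, quantile normalization or scaling without the highest genes, the rescalings that turned the excess of differing genes to liver. Whether muscle would keep more detected genes under those rescalings was not tested. Genes in liver alone went from 562 to 178 at any RPKM above 0, and those in muscle alone from 2601 to 1459 there and to 1291 at 5 RPKM. The 10 highest genes held 35.6% of reads in liver and 14.3% in muscle, the recovered reads being lower bounds.

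Liver loci found in muscle were 91.3% with 50% overlap, 95.6% with 2 or more exons, 90.5% with muscle assembly 2 alone and 88.7% with assembly 3 alone. Muscle loci found in liver were 52.2% with 50% overlap, 74.0% with 2 or more exons and 71.1% for assembly 3 alone. Agreement of the muscle assemblies was 72.1% and 93.0% with 50% overlap, and 87.7% of assembly 2 with 2 or more exons. The cause was not tested for these. Of the 24 alternative differences of the 4 named genes 0 changed sign, and the smallest was 6.97. The largest shifts were with subtracted carry-over, from 7.52 to 13.10 and from 7.32 to 11.48 for the liver-high genes. Counts without shared symbols, shares without mitochondrial genes and gene lists were not run, as they need gene names. No paired analysis was possible because there is 1 sample per tissue. Depth limits how exactly the lower value of a difference is known. At most 232 of the 685 solved muscle-high genes had fewer than 20 liver reads, as recovered reads are lower bounds. The unsolved muscle-high genes, listed at 0 RPKM in liver, come on top of these. For the same reason, at most 39 liver-high genes had fewer than 20 reads in each muscle library.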

Other observations

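The first test of neighbouring genes and that of row order were chosen after the pattern was seen; the one of genes 3 numbers apart was written before its result. The 2 muscle libraries differed in 1 direction: of 11747 genes, 149 were at least 4-fold lower in the smaller library and 0 were 4-fold higher, with log2 ratios from -4.40 to 1.90. These 149 genes lay on 122 scaffolds. Their median was 0.616 RPKM in muscle and 0.0472 RPKM in liver, and 24 of them were among the genes 4-fold higher in muscle.

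Liver introns missing from muscle shared ends with introns of the other tissue more often than muscle introns missing from liver. Of 9103 such liver introns, 37.5% (Wilson 95% interval 36.6 to 38.5) shared exactly 1 end with a muscle intron and 7.61% (7.09 to 8.18) joined 2 ends both used in muscle. Of 21530 introns found in both muscle assemblies and missing from liver, 8.73% (8.36 to 9.11) shared 1 end with a liver intron and 1.12% (0.992 to 1.27) joined 2 known ends. Liver introns were counted from 1 assembly and those of muscle had to be in both, so the sets are not of equal stringency. Introns were also not limited to loci assembled in both tissues. Of liver loci 93.3% overlapped a muscle locus, but of muscle loci 61.2% overlapped a liver locus. An intron of a locus missing from the other tissue cannot share an end there. The contrast may therefore reflect missing loci and not the kind of intron.

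Genes with neighbouring numbers on a scaffold tended to be higher in the same tissue, taking the numbers as the order along the scaffold, which was not checked. Over 11830 pairs of consecutive genes, the difference between the tissues correlated with r = 0.177, against a highest value of 0.0281 in 1000 permutations, a correlation across genes. Both genes were 4-fold higher in liver in 32 pairs (highest of the permutations 16) and in muscle in 71 pairs (highest 39), while the 15 opposite pairs lay within the permutations (11 to 39). A hypothesis is that neighbouring genes share their tissue. The correlation lay mostly between direct neighbours: r was 0.0457 at 2 numbers apart, 0.00571 at 5 and -0.00739 at 10. At 3 numbers apart r was 0.0303, between the bounds set for a gene split into adjacent models or reads shared by neighbours. Those explanations thus cannot be told apart from the hypothesis of a shared tissue here.

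The first 5366 rows of the deposited table were not in ID order, while the other 10031 were. Within the first rows the absolute log2 ratio of the tissues was lower at higher row numbers (Spearman's rho -0.622, across genes), from a median of 6.72 in the first 500 rows. A hypothesis consistent with this is that rows were ranked by a test of liver against muscle; no such test was used here.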
